A study of Homo sapiens with 28 samples.

How the data were processed

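The samples were 28 arrays of the HT-12 bead platform, hybridised with RNA from 12 groups of cells in 3 experiments. Per the labels' protocols, cells were grown in RPMI 1640 medium with serum, compounds were dissolved in DMSO, untreated cultures received DMSO alone, and RNA was extracted with TriZOL and the RNAqueous kit, amplified and labelled with biotin. Arrays were read with GenomeStudio, per the submitters' processing notes. The first deposited table holds the mean bead signal of 47231 probes on each array as a linear intensity without background correction, with a detection p-value per probe, per the file headers. The second deposited table holds intensity values after background subtraction by the authors, with the same detection p-value columns. Between the 2 tables each array differs by a constant of 42.1 to 60.0 units. The third table holds 38220 probes with an intensity normalized by the authors by a method not given in the sources used here. Its array medians run from 23.6 to 25.3, so the scale is linear and the values are not centred, while the method behind them stays unknown; each of its columns correlates best with the array of the same label (r of 0.974 to 0.993). Its values do not enter the main results.

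The uncorrected signals were processed with the neqc function of limma 3.58.1 in R 4.3.3, which corrects the background with a normal and exponential model, adds an offset (16), takes log2 and quantile-normalizes the 28 arrays together. The files hold no control probes, so the mean and spread of the background were inferred by limma from the detection p-values, whose steps correspond to 770 negative controls. Tables were read with the data.table package (version 1.17.8), and figures were drawn with matplotlib 3.10.9 under Python 3.11.15. A probe was kept in an experiment when its detection p lay under 0.01 on at least as many arrays as the smallest group has (3 in the JeKo-1 course, 2 in the others). Of the probes, 27004 carried 1 gene symbol in the platform table, 4 several and 20223 none; 26970 of the named probes had a gene ID in the gene table and took its current symbol, and 34 kept the symbol given. Each gene was represented by its probe with the highest mean over the 28 arrays.

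Median signals ran from 47.5 to 68.7 units, and 29.7% to 35.2% of the probes were detected per array. The SD of an array from its group mean was 0.155 to 0.200 (log2) over the probes kept, and the number of arrays limits the precision. No array was left out, and no value column lacked a sample.

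Each experiment was fitted with limma on its groups, with moderated t tests, Benjamini-Hochberg adjustment over the genes of a comparison and a threshold of 0.05 on the adjusted p. There were 10 main comparisons: 3 times with ONC201 against 0 h in JeKo-1; ONC201 against control in parental and in resistant Z138, untreated resistant against parental, and the resistant minus the parental effect; and tunicamycin at 12 h and 24 h and rapamycin at 24 h against the untreated cells at 24 h. Added to these were a moderated F test over the times, and tests of the difference of 2 effects from 2 experiments (ONC201 at 24 h in JeKo-1 minus tunicamycin, minus rapamycin and minus parental Z138). The differences to tunicamycin and rapamycin were fitted over the 20 JeKo-1 arrays. The difference to Z138 was fitted over all 28 arrays, with genes that passed the detection filter in all 3 experiments. Comparisons, tests, gene lists and the alternatives named below were fixed before the data were examined, apart from the comparison of 36 h with 24 h in JeKo-1 and the tests of explanations that the additional observations name as chosen later. Gene lists (28, written from general knowledge) were tested with camera at its preset correlation of 0.01, and again with a correlation estimated from the residuals, where at least 5 members were measured; the list of transcripts encoded in the mitochondrial genome had 0 measured members. The lists overlap, as the stress response list shares genes with the lists of amino acid synthesis, tRNA synthetases and mTORC1 regulators. List p-values were adjusted over the main comparisons together, and separately over the differences between experiments, over the added comparison and over the signature tests. Correlations of fold changes that share control arrays were set beside 20 simulations of unchanged groups.

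Genes named in the text come from a rule: a panel of 30 genes for stress responses, cell cycle, mantle cell lymphoma and drug targets; the 10 genes called with the largest rise and the 10 with the largest fall per comparison whose arrays do not overlap between groups; and up to 4 members per list with the largest change. For differences between 4 groups the condition on overlap does not apply. Loci without an official symbol were counted and not named. The text leaves out some genes of this rule, so a gene named is not always among the largest changes. Where every array of a group had a detection p of 0.01 or more for a probe, the fold is a bound: the mean of the detected group minus the mean, over the arrays of the other group, of the higher of the lowest detected log2 level of the array and the value of the probe. No bound was formed for differences of 2 effects.

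The steps were tested on simulated log2 values with the real genes and group sizes. In each comparison 100 genes were changed by each size, and all others were left unchanged. Noise was independent between genes, with the spread fitted by limma. Where more genes change, the Benjamini-Hochberg adjustment asks less of each gene. The shares below thus do not carry over directly to the real comparisons. Of genes changed by 1 (log2), 95% to 99% were called in the main comparisons except the resistant minus parental difference, with 88%, and 85%, 93% and 95% in the differences to tunicamycin, to rapamycin and to Z138; the F test called 100%. Of genes changed by 0.5, limma called 84%, 71% and 77% at 12, 24 and 36 h in JeKo-1, 63% in parental Z138, 52% in resistant Z138, and 47% for untreated resistant cells. It called 5% in the resistant minus parental difference, 37% and 48% for tunicamycin at 12 h and 24 h, 46% for rapamycin, 74% in the F test, and 25%, 32% and 32% in the differences to tunicamycin, to rapamycin and to Z138. At most 0.186% of unchanged genes were called, and 0 changed genes were called in the wrong direction.

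The alternatives tried for the values were: no background correction; the authors' background-corrected and normalized values; an offset of 50; and normalization of each experiment alone. For the tests they were: no detection filter and a strict one (detected on every array of at least 1 group); all probes instead of 1 per gene; 1 fit over all arrays; trend and robust variance moderation; the replicate number as a block; calls of at least 1.5-fold; each array left out in turn; camera with an estimated correlation and the fry test; and smaller or larger signatures.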

Results

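Gene expression was measured in 2 human mantle cell lymphoma lines, JeKo-1 and Z138, which are established cultures of malignant B cells. The 28 bead arrays came from 3 experiments. In the first, JeKo-1 cells were harvested at 0 h and after 12, 24 and 36 h with ONC201, a small molecule developed as a cancer drug and known to activate the mitochondrial protease CLPP, with 3 wells per time. The labels give no dose for this course. In the second, Z138 cells that were either parental or resistant to ONC201 were left untreated or given 5 µM ONC201 for 24 h, with 2 wells per group. In the third, JeKo-1 cells received 1 µM tunicamycin for 12 or 24 h, or 10 nM rapamycin for 24 h, beside untreated cells harvested at 24 h, again with 2 wells per group. Tunicamycin blocks N-linked glycosylation, so that misfolded proteins build up in the endoplasmic reticulum, and rapamycin inhibits the growth-promoting kinase complex mTORC1. Between 29.7% and 35.2% of the probes were detected on each array, and the median signal of an array ran from 47.5 to 68.7 intensity units. The wells of an experiment were seeded from one stock culture per line, so p-values measure the spread between wells, which may be technical, and the small number of arrays limits the precision. Each experiment had a chip of its own, and the place of an array on the chip followed the order of the groups, so group and place cannot be separated. Changes are log2 fold changes ± the standard error from limma, and a gene was called at an adjusted p under 0.05. Where no array of a group detected a gene's probe, only a bound on the fold is given, computed against the lowest detected signal of those arrays.

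To follow the response of JeKo-1 cells over time, each time with ONC201 was compared with the untreated cells at 0 h, so each change also holds the time in culture. At 12 h (n = 3 per group), genes of the integrated stress response, a programme switched on when the translation factor eIF2 is phosphorylated, were already higher. TRIB3, a pseudokinase gene activated by ATF4 and CHOP, rose by 1.69 ± 0.08, STC2 by 1.69 ± 0.09, the mTORC1 inhibitor DDIT4 by 1.27 ± 0.09, ATF3 by 1.24 ± 0.13, and DDIT3, which encodes CHOP, by 0.80 ± 0.08. SESN2, another inhibitor of mTORC1 signalling, was at least 1.45-fold higher, while ATF4 itself, at 0.09 ± 0.07, was not called. Of the 30 measured members of this list, 18 rose, 0 fell and 12 were not called (22 higher and 0 lower when adjusted over the list alone; camera, adjusted p = 5.04e-24). Chaperones of the endoplasmic reticulum went the other way: HSPA5, which encodes the chaperone BiP, fell by 0.95 ± 0.08, SDF2L1 fell by 0.69 ± 0.10 and HSP90B1 fell by 0.54 ± 0.06. In that list of 28 genes, 6 fell and 1 rose (9 lower and 1 higher when adjusted over the list alone; camera, adjusted p = 9.06e-07). Among 21 genes of sterol and fatty acid synthesis, 8 fell and 0 rose (14 lower when adjusted over the list alone; camera, adjusted p = 7.39e-09). HMGCS1, which makes the precursor of mevalonate, fell by 0.61 ± 0.08 and MSMO1 fell by 0.54 ± 0.08. ID1, first among the rises named by the rule, was at least 2.92-fold higher. CD1C, a lipid-presenting surface protein, fell by 1.15 ± 0.11, and the mitochondrial gluconeogenic enzyme PCK2 rose by 1.16 ± 0.07. In total, limma called 337 of 8823 genes (191 higher, 146 lower), 14 of them changed at least 2-fold. In all 337 the 3 treated arrays did not overlap the 3 controls. Chance gives this in 10% of genes not chosen by a test, but the calling itself favours it, so it is no separate support. The count was 159, 166 or 181 without 12 h replicate 1, 2 or 3, and 203 or 191 without 0 h replicate 1 or 3.

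At 24 h TRIB3 rose by 3.66 ± 0.08 relative to 0 h, DDIT3 by 2.18 ± 0.08, the tryptophanyl-tRNA synthetase WARS1 by 2.15 ± 0.08 and PPP1R15A, a phosphatase subunit that reverses eIF2 phosphorylation, by 1.33 ± 0.09 (n = 3 per group). The amino acid synthesis enzymes PSAT1 and ASNS rose by 1.31 ± 0.06 and 1.24 ± 0.08. TNFRSF10B, the death receptor DR5, rose by 0.75 ± 0.09, and SESN2 was at least 3.47-fold higher. STC2 and DDIT4 stood at 8.72 and 10.55 (log2) with ONC201 at 24 h and at 6.05 and 8.22 at 0 h, while untreated cells at 24 h, on the chip of the third experiment, stood at 8.05 and 10.10. Time and chip are not separable there. Of the list, 28 of the 30 stress response genes rose with 0 lower (29 higher when adjusted over the list alone; camera, adjusted p = 5.04e-24). The reticulum genes split. HSPA5 fell by 1.25 ± 0.08, SDF2L1 fell by 1.37 ± 0.10 and the lectin chaperone CALR fell by 1.06 ± 0.08, whereas the co-chaperone DNAJB9 rose by 0.91 ± 0.10 and the transcription factor XBP1 by 0.46 ± 0.07. With 11 of 28 lower and 7 higher, also when adjusted over the list alone, the list as a whole was not called (camera, adjusted p = 0.119). HMGCS1 fell by 1.57 ± 0.08, the fatty acid synthase FASN fell by 1.18 ± 0.09 and DHCR7, the last enzyme of cholesterol synthesis, fell by 1.10 ± 0.11. Of the 21 sterol and fatty acid genes, 16 fell and 0 rose, also when adjusted over the list alone (camera, adjusted p = 6.47e-10). Cytosolic heat shock genes fell in 10 of 13 cases, with 0 higher and the same count when adjusted over the list alone (camera, adjusted p = 1.5e-08). Among them HSPH1 fell by 1.21 ± 0.07, HSPA8 fell by 1.13 ± 0.09 and HSPA1B, whose probe may also read its near-identical neighbour HSPA1A, fell by 1.24 ± 0.09.

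At 24 h RRM2, a subunit of ribonucleotide reductase, fell by 1.16 ± 0.19, the cyclin CCNE1 fell by 0.58 ± 0.10, and the primase subunit PRIM1 rose by 0.88 ± 0.07. Of 36 genes of DNA replication 15 fell and 4 rose (17 and 4 when adjusted over the list alone; camera, adjusted p = 0.00267). The proliferation marker MKI67 fell by 0.58 ± 0.09. Of the genes of mitosis 17 of 39 were lower and 1 higher (19 and 1 when adjusted over the list alone; camera, adjusted p = 0.000304, but adjusted p = 0.164 with an estimated correlation). MYC itself rose by 0.29 ± 0.06. Among 34 MYC targets and genes of ribosome assembly 21 fell and 2 rose (22 and 2 when adjusted over the list alone; camera, adjusted p = 5.05e-06). RRP12 fell by 0.78 ± 0.07 and NOP16 fell by 0.71 ± 0.08. The B-cell antigen MS4A1, or CD20, fell by 1.13 ± 0.11, the surrogate light chain gene VPREB1 fell by 1.68 ± 0.13 and the receptor component CD79A fell by 0.65 ± 0.06. In the B-cell list of 25 genes, 13 fell and 3 rose, also when adjusted over the list alone (camera, adjusted p = 0.0054, but adjusted p = 0.125 with an estimated correlation). Of the nuclear genes for mitochondrial proteins, 18 of 49 mitochondrial ribosomal protein genes fell and 0 rose, also when adjusted over the list alone (camera, adjusted p = 0.00176, but adjusted p = 0.27 with an estimated correlation). Among the 50 subunits of oxidative phosphorylation 12 fell and 2 rose (10 and 2 when adjusted over the list alone; camera, adjusted p = 0.00793, but adjusted p = 0.341 with an estimated correlation). The mitochondrial protease LONP1 rose by 0.95 ± 0.08, while CLPP, at -0.03 ± 0.08, and its partner CLPX, at 0.14 ± 0.07, were not called. Among death genes, the BH3-only genes HRK and PMAIP1 rose by 0.97 ± 0.10 and 0.75 ± 0.17 and the anti-apoptotic BCL2 by 0.83 ± 0.08. Of these 17 genes 8 rose and 1 fell (8 and 2 when adjusted over the list alone), and the list was not called (camera, adjusted p = 0.0535). For plasma cell markers the median was 0.03, the mean -0.05 and the direction of camera higher, at an adjusted p of 0.952. In total limma called 3383 of 8823 genes (1754 higher, 1629 lower), 188 of them changed at least 2-fold (132 higher, 56 lower), and 3273 without overlap of the 3 and 3 arrays.

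**Figure D1:**
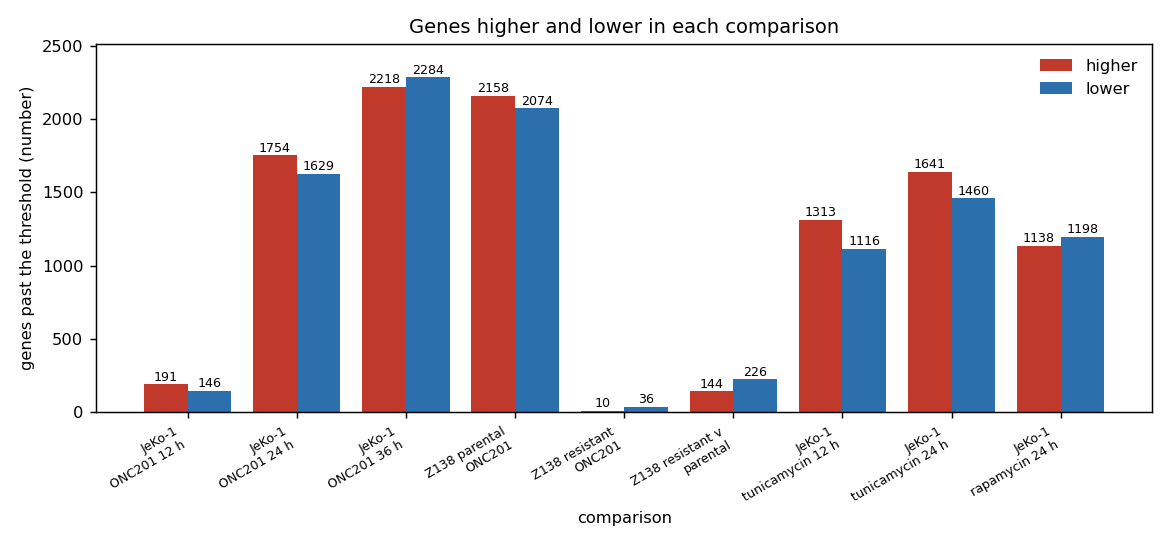
Number of genes called higher and lower by limma in each comparison (bars, from 0). ONC201 gave 337, 3383 and 4502 genes at 12, 24 and 36 h in JeKo-1, 4232 in parental Z138 and 46 in resistant Z138 cells.

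At 36 h, TRIB3 rose by 3.98 ± 0.08, WARS1 by 2.83 ± 0.08, DDIT3 by 2.62 ± 0.08, PPP1R15A by 2.53 ± 0.09 and TNFRSF10B by 1.21 ± 0.09 relative to 0 h (n = 3 per group). The largest rises named by the rule were PRPH, at least 21.2-fold higher, and then CCPG1, which rose by 4.30 ± 0.17. All but 1 of the 30 stress response genes rose and 0 fell (30 higher when adjusted over the list alone; camera, adjusted p = 4.93e-20). DNAJB9 rose by 1.99 ± 0.10, XBP1 by 1.34 ± 0.07 and the translocon subunit SEC61A1 by 1.19 ± 0.10, while HSPA5, at -0.10 ± 0.08, was no longer called. The reticulum list now had 18 genes higher and 5 lower of 28, also when adjusted over the list alone (camera, adjusted p = 0.00229, but adjusted p = 0.0521 with an estimated correlation). The autophagy genes WIPI1 and MAP1LC3B rose by 2.81 ± 0.18 and 1.70 ± 0.07. In that list 16 of 31 autophagy and lysosome genes rose with 4 lower (16 and 5 when adjusted over the list alone; camera, adjusted p = 0.00757, but adjusted p = 0.0551 with an estimated correlation). MKI67 fell by 1.32 ± 0.09, the mitotic kinase PLK1 fell by 1.39 ± 0.16 and RRM2 fell by 1.87 ± 0.19. Of the mitosis genes 36 of 39 fell and 0 rose (37 and 1 when adjusted over the list alone; camera, adjusted p = 6e-12). Of the replication genes 29 of 36 fell and 2 rose (30 and 2 when adjusted over the list alone; camera, adjusted p = 2.46e-07). Subunits of the respiratory chain and ATP synthase fell in 30 of 50 cases with 0 higher (32 when adjusted over the list alone; camera, adjusted p = 1.76e-06, but adjusted p = 0.135 with an estimated correlation). UQCRB fell by 1.30 ± 0.08 and ATP5MC1 fell by 1.27 ± 0.07. VPREB1 was at least 8.25-fold lower, and the lymphocyte antigen CD52 fell by 2.23 ± 0.10. In total limma called 4502 genes (2218 higher, 2284 lower), 481 of them changed at least 2-fold, and 4348 without overlap of the arrays. Over the 3 times together, the moderated F test of limma called 4530 genes.

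The 36 h and 24 h groups were then compared with each other, a comparison chosen after the data had been seen. HSPA5 was higher by 1.15 ± 0.08 at 36 h, XBP1 by 0.87 ± 0.07, DNAJB9 by 1.08 ± 0.10 and HSP90B1 by 0.72 ± 0.06 (n = 3 per group). Of the 28 reticulum genes 24 were higher and 0 lower (25 and 1 when adjusted over the list alone; camera, adjusted p = 1.07e-20, and 0.000213 with an estimated correlation). Genes of mitosis were lower in 27 of 39 cases and higher in 0 (35 lower when adjusted over the list alone; camera, adjusted p = 6.23e-19), with MKI67 at -0.73 ± 0.09. Of 36 replication genes 19 were lower and 0 higher (25 and 1 when adjusted over the list alone; camera, adjusted p = 9.5e-12). Limma called 1275 genes between the 2 times (612 higher, 663 lower).

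**Figure D2:**
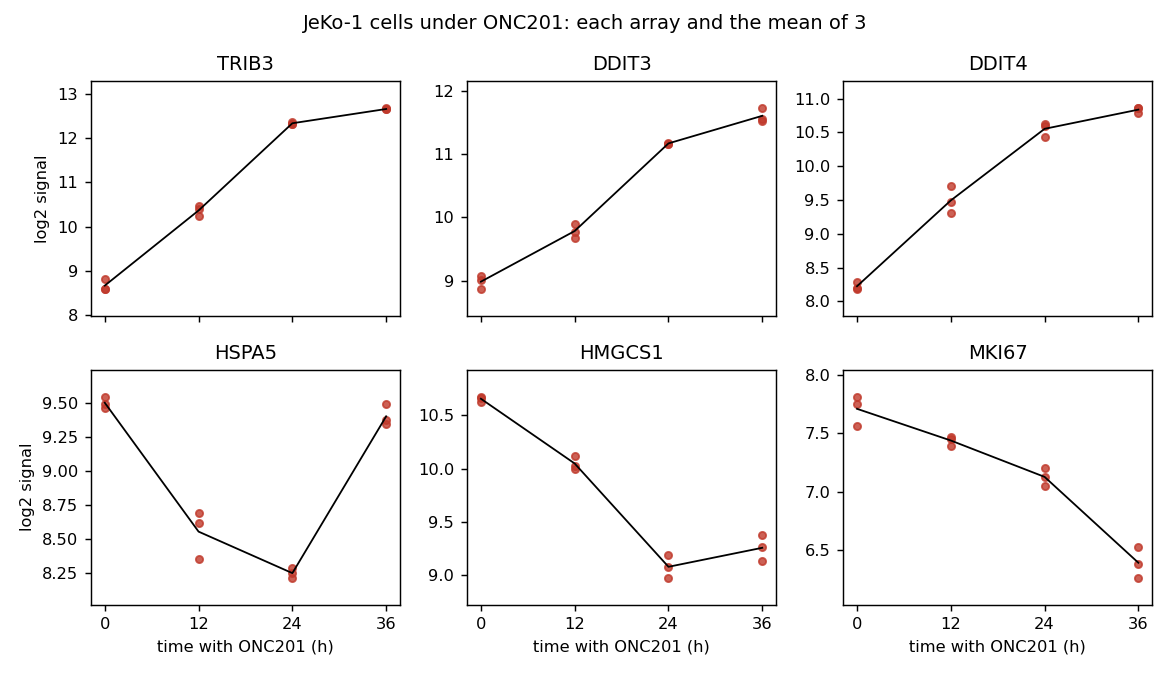
Signal (log2) of TRIB3, DDIT3, DDIT4, HSPA5, HMGCS1 and MKI67 in JeKo-1 cells against time with ONC201 in h. Points are arrays and lines the mean of 3; TRIB3 lies 3.98 above its 0 h mean at 36 h, and HSPA5 drops by 1.25 at 24 h and returns to within 0.10 of its 0 h mean at 36 h.

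Across genes, which are not independent replicates, the fold changes at 24 h and 36 h had a Pearson r of 0.891, those at 12 h and 24 h an r of 0.712, and those at 12 h and 36 h an r of 0.549. Comparisons that share the 0 h arrays are correlated without any effect, and simulated unchanged groups gave r values of 0.50 for each of the 3 pairs. The covariance was 0.177 at 24 and 36 h against 0.00668 in the simulation, 0.0531 at 12 and 24 h against 0.00666, and 0.0552 at 12 and 36 h against 0.0066. The difference estimates the shared effect, and part of the excess in shared calls may come from the shared controls. Of the genes called, 1497 were higher at both 24 h and 36 h, where independent lists would share 441, and 1409 were lower at both against 422. At both 12 h and 36 h 171 were higher against 48, and 124 lower against 38.

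To ask whether a second line responded in the same way, parental Z138 cells were compared with and without 5 µM ONC201 at 24 h (n = 2 per group). PPP1R15A rose by 2.94 ± 0.09, TRIB3 by 2.88 ± 0.09, DDIT3 by 2.62 ± 0.10, DDIT4 by 2.60 ± 0.09, SESN2 by 2.05 ± 0.09 and TNFRSF10B by 0.99 ± 0.09. Of 30 stress response genes 28 rose and 0 fell, also when adjusted over the list alone (camera, adjusted p = 2.49e-16). The reticulum genes rose too, 27 of 29 with 0 lower, also when adjusted over the list alone (camera, adjusted p = 1.81e-13). DNAJB9 rose by 2.44 ± 0.12, the coat protein gene SEC24D by 2.26 ± 0.15, HSPA5 by 1.61 ± 0.10 and XBP1 by 1.37 ± 0.11. The adaptor PAG1 rose by 3.92 ± 0.11 and CCPG1, a receptor for degradation of the reticulum, by 3.63 ± 0.10. Replication genes fell in 32 of 36 cases and rose in 1, also when adjusted over the list alone (camera, adjusted p = 6.24e-12). CCNE1 fell by 1.67 ± 0.17 and the thymidine kinase TK1 fell by 1.52 ± 0.10. Mitosis genes fell in 29 of 39 cases and rose in 1 (34 and 1 when adjusted over the list alone; camera, adjusted p = 2.67e-08, but adjusted p = 0.0768 with an estimated correlation). Heat shock genes fell in 12 of 16 cases and rose in 1 (13 and 1 when adjusted over the list alone; camera, adjusted p = 1.06e-05, but adjusted p = 0.071 with an estimated correlation). MS4A1 fell by 1.61 ± 0.15 and VPREB3 fell by 1.62 ± 0.13, while SOX11, a transcription factor typical of this lymphoma, rose by 1.03 ± 0.10. CCND1, the cyclin activated by the translocation of this lymphoma, fell by 0.41 ± 0.10. ID3, a repressor of E proteins, fell by 2.44 ± 0.09. Limma called 4232 of 9453 genes (2158 higher, 2074 lower), 523 of them changed at least 2-fold (317 higher, 206 lower).

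To ask how resistant Z138 cells responded to the same exposure, they were compared with and without 5 µM ONC201 at 24 h (n = 2 per group). None of the 30 stress response genes passed over all genes: TRIB3 stood at 0.42 ± 0.09, SESN2 at 0.45 ± 0.09, DDIT3 at 0.33 ± 0.10 and PPP1R15A at 0.04 ± 0.09. Adjusted over the list alone, 8 were higher and 0 lower, and the list lay higher as a whole (camera, adjusted p = 1.88e-05, but adjusted p = 0.0666 with an estimated correlation). HSPA5, at 0.27 ± 0.10, and DNAJB9, at -0.03 ± 0.12, were not called, nor was the reticulum list, where 1 gene was higher and 1 lower when adjusted over the list alone (camera, adjusted p = 0.218). The genes that limma did call included PTMA, a histone-binding protein gene that fell by 1.10 ± 0.14, the zinc finger gene MAZ, which fell by 1.06 ± 0.13, and the adaptor YWHAE, which fell by 0.90 ± 0.13. Higher were the circadian regulator CLOCK, which rose by 0.91 ± 0.13, and PRKDC, the catalytic subunit of DNA-dependent protein kinase, which rose by 0.91 ± 0.13. They numbered 46 of 9453 (10 higher, 36 lower), with 1864 at an unadjusted p under 0.05. Leaving out any of the 4 resistant arrays, treated replicate 1 or 2 or control replicate 1 or 2, left 0 calls in limma. The count and the share of higher genes also moved with the processing: 418 genes without background correction (176 higher, 242 lower), 454 with an offset of 50 (198 higher, 256 lower), and 0 with the authors' normalized values.

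The resistant and parental responses were compared directly by testing the resistant effect minus the parental effect (n = 2 in each of 4 groups). Here lower and higher refer to this difference of effects and not to levels. PPP1R15A differed by -2.90 ± 0.13, TRIB3 by -2.46 ± 0.12, DDIT3 by -2.29 ± 0.15 and DDIT4 by -2.28 ± 0.13. Of the stress response genes 22 of 30 were lower in the difference with 0 higher (24 lower when adjusted over the list alone; camera, adjusted p = 1.57e-13). DNAJB9 differed by -2.46 ± 0.17, SEC24D by -2.26 ± 0.21 and HSPA5 by -1.34 ± 0.14, as part of 25 of 29 reticulum genes that were lower and 0 higher (28 lower when adjusted over the list alone; camera, adjusted p = 5.12e-13). Replication genes were higher in 28 of 36 cases and lower in 1 (30 and 1 when adjusted over the list alone; camera, adjusted p = 2.06e-12), for example CCNE1 by 1.82 ± 0.24 and TK1 by 1.59 ± 0.14. Limma called 2886 genes in this difference (1345 higher, 1541 lower), 599 of them by at least 2-fold. The fold changes of the parental and resistant cells, which share no array, had an r of 0.0738 across genes.

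**Figure D3:**
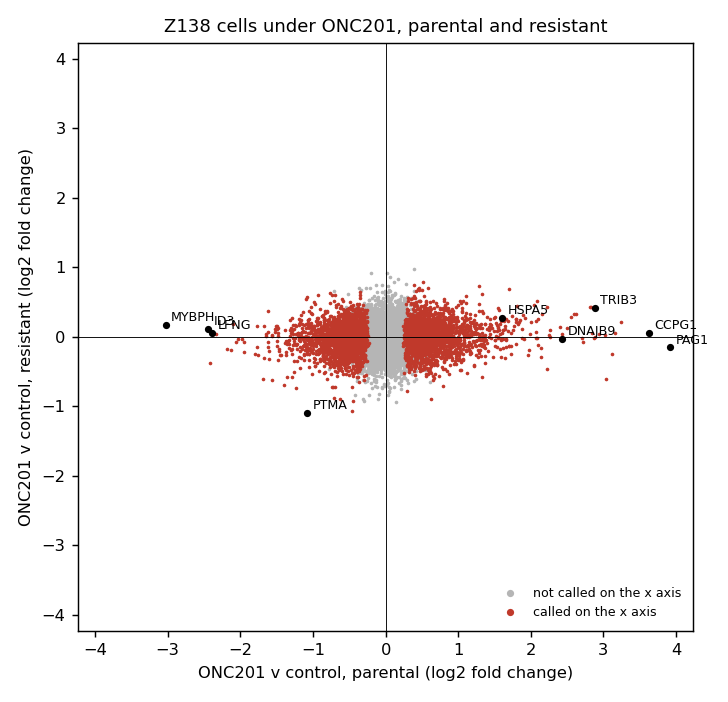
Log2 fold change under ONC201 in resistant Z138 cells (vertical) against parental Z138 cells (horizontal); each point is a gene and red points are the 4232 genes called in parental cells. The red points spread along the horizontal axis, and r across genes is 0.0738.

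Untreated resistant cells were compared with untreated parental cells to ask how the lines differed without treatment (n = 2 per group). The labels do not say how the resistant line was derived or whether it had been kept with the compound. The immediate early gene EGR1 fell by 4.0 ± 0.10, and FOS, of the same class, was at least 5.35-fold lower. The chemokine gene CCL3L3, whose probe may also read its near-identical copies CCL3 and CCL3L1, fell by 2.41 ± 0.12. Of 24 genes induced by NF-kB and the B-cell receptor 9 were lower and 0 higher (11 and 1 when adjusted over the list alone; camera, adjusted p = 1.7e-10). Polyadenylated histone transcripts were lower in 9 of 20 cases and higher in 0 (12 lower when adjusted over the list alone; camera, adjusted p = 6.48e-12), among them H1-2, which fell by 1.25 ± 0.10, and H2BC5, which fell by 0.97 ± 0.12. BCL2L2, an anti-apoptotic member of the BCL2 family, fell by 1.38 ± 0.11, and BEX3 and PLAC8 fell by 2.60 ± 0.11 and fell by 2.11 ± 0.10. DDIT4 and PPP1R15A were lower as well, as they fell by 0.73 ± 0.09 and fell by 0.76 ± 0.09, within a stress response list where 5 of 30 were lower and 1 higher (6 and 1 when adjusted over the list alone; camera, adjusted p = 7.34e-07). Higher in resistant cells were the heat shock gene HSPA1B, by 1.37 ± 0.09, VPREB1, by 1.19 ± 0.13, and the RNA-binding protein gene YBX3, by 1.17 ± 0.11. Limma called 370 of 9453 genes (144 higher, 226 lower), 67 of them by at least 2-fold (10 higher, 57 lower). The count was 114 or 106 without resistant control replicate 1 or 2, and 137 or 181 without parental control replicate 1 or 2.

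The 100 genes that rose most and the 100 that fell most at 24 h in JeKo-1 cells were then followed in the other experiments, which share no array with that course. In parental Z138 cells 71 of the 84 measured rising genes were higher and 2 lower (camera, adjusted p = 2.44e-26, and 0.00321 with an estimated correlation). Of the 87 measured falling genes 47 were lower and 5 higher (camera, adjusted p = 4.35e-09, and 0.00321 with an estimated correlation). In resistant cells under ONC201 0 of the 84 were called, with 59 positive and 25 negative differences (camera, adjusted p = 0.000457, but adjusted p = 0.0633 with an estimated correlation), and of the 87 falling genes 1 was higher and 0 lower (camera, adjusted p = 0.677). Without treatment, 14 of the 84 were lower in resistant than in parental cells and 0 higher (camera, adjusted p = 1.63e-07, and 0.0233 with an estimated correlation). Of the 87 falling genes 6 were higher and 2 lower (camera, adjusted p = 0.0396, but adjusted p = 0.0569 with an estimated correlation).

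The 24 h effects of ONC201 in JeKo-1 and parental Z138 cells were set against each other by testing their difference, which also holds the difference between the 0 h control of JeKo-1, the 24 h control of Z138, 2 chips and a dose not known for JeKo-1. HSPA5, which fell in one line and rose in the other, differed by -2.86 ± 0.12 (n = 3 per group in JeKo-1 and 2 in Z138), SDF2L1 by -2.26 ± 0.15, HSP90B1 by -2.03 ± 0.09 and HYOU1 by -1.80 ± 0.21. Lower and higher refer here to the effect in JeKo-1 minus that in Z138 and not to levels. In the reticulum list 26 of 28 genes were lower and 0 higher (28 lower when adjusted over the list alone; camera, adjusted p = 8.6e-27). HMGCS1 differed by -2.04 ± 0.12. The stress response list was not called: 9 of 29 were higher and 5 lower, also when adjusted over the list alone (camera, adjusted p = 0.772, with a median of 0.05 and a mean of -0.02). TRIB3 differed by 0.78 ± 0.10 and PPP1R15A by -1.61 ± 0.13. Replication genes were higher in this difference in 27 of 36 cases and lower in 0 (30 higher when adjusted over the list alone; camera, adjusted p = 1.55e-13), for example TK1 by 1.39 ± 0.11. As a list these genes fell in both lines, less so in JeKo-1. Limma called 2234 of 8164 genes (1122 higher, 1112 lower). Across genes the 2 effects had an r of 0.541, and 858 genes rose and 817 fell in both, where independent lists would share 372 and 356.

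Tunicamycin served as a known inducer of reticulum stress in JeKo-1 cells; both times were compared with the untreated cells at 24 h, so the 12 h comparison also holds 12 h of culture (n = 2 per group). At 12 h TRIB3 rose by 2.92 ± 0.09, WARS1 by 2.62 ± 0.09, DDIT3 by 2.38 ± 0.13, the chaperone HYOU1 by 2.06 ± 0.17 and DNAJB9 by 1.86 ± 0.09. At 24 h TRIB3 rose by 2.95 ± 0.09, DNAJB9 by 2.55 ± 0.09, HYOU1 by 2.45 ± 0.17 and HSPA5 by 0.82 ± 0.09. Of 29 reticulum genes 27 rose at 12 h and 28 at 24 h with 0 lower, the same counts when adjusted over the list alone (camera, adjusted p = 9.78e-15 and 1.48e-17). Of 31 stress response genes 29 and 30 rose with 0 lower, and 30 at each time when adjusted over the list alone (camera, adjusted p = 4.93e-20 and 1.99e-18; at 24 h adjusted p = 0.0517 with an estimated correlation). Genes induced by NF-kB and the B-cell receptor fell in 14 of 25 cases at 12 h and 20 at 24 h, with 1 higher at each time (17 and 22 lower when adjusted over the list alone; camera, adjusted p = 5.02e-09 and 7.02e-12). EGR1 fell by 2.20 ± 0.08 and the activation marker CD83 fell by 2.65 ± 0.13 at 24 h. HMGCS1 fell by 1.91 ± 0.09 at 12 h and fell by 1.34 ± 0.09 at 24 h. Of 23 sterol and fatty acid genes 11 and 14 were lower and 0 higher (13 and 15 when adjusted over the list alone; camera, adjusted p = 1.12e-06 and 3.55e-06). The glycolytic enzyme gene ALDOC fell by 3.66 ± 0.15 at 24 h. Of the glycolysis genes 16 of 19 were lower and 1 higher (17 and 1 when adjusted over the list alone; camera, adjusted p = 3.74e-08, but adjusted p = 0.0776 with an estimated correlation). The phosphatase gene PTPN6 fell by 4.64 ± 0.17, and CYTL1 was at least 21.5-fold higher.

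Limma called 2429 of 9517 genes at 12 h (1313 higher, 1116 lower), 290 of them at least 2-fold, and 3101 at 24 h (1641 higher, 1460 lower), 497 of them at least 2-fold. At 12 h the count was 1395 or 1475 without treated replicate 1 or 2 and 1379 or 1515 without control replicate 1 or 2, and at 24 h it was 2016 without treated replicate 1 and 2048 without control replicate 1. Among the signature genes of ONC201 at 24 h, 82 of 98 rising genes were higher under tunicamycin at 24 h and 2 lower (camera, adjusted p = 5.97e-30, and 0.00235 with an estimated correlation). There 51 of 97 falling genes were lower and 10 higher (camera, adjusted p = 5.37e-12, and 0.0167 with an estimated correlation).

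Rapamycin at 24 h tested inhibition of mTORC1 in the same line (n = 2 per group). Here the stress response genes fell. ATF5 fell by 3.14 ± 0.09, DDIT4 fell by 2.61 ± 0.14, STC2 fell by 2.57 ± 0.11, TRIB3 fell by 1.72 ± 0.09, ASNS fell by 1.40 ± 0.11 and DDIT3 fell by 1.31 ± 0.13. These falls also hold the level of the 24 h control. It stood at 12.35 (log2) for ATF5, 10.10 for DDIT4, 8.05 for STC2 and 9.69 for TRIB3, against 11.55, 8.22, 6.05 and 8.67 at 0 h on another chip and 9.21, 7.50, 5.48 and 7.97 under rapamycin. Of the 31 members 28 fell and 0 rose (29 lower when adjusted over the list alone; camera, adjusted p = 2.54e-19). Glycolysis genes fell in 16 of 19 cases with 0 higher, also when adjusted over the list alone (camera, adjusted p = 6.48e-12, but adjusted p = 0.0517 with an estimated correlation). ALDOC fell by 3.34 ± 0.15 and the triose phosphate isomerase TPI1 fell by 1.48 ± 0.08, and PFKFB4, a regulator of glycolysis, was at least 13.5-fold lower. In the untreated cells at 0 h of the ONC201 course, on another chip, PFKFB4 was not detected and ALDOC stood at 9.14 (log2), against 9.06 and 10.80 in the 24 h control, which also served for tunicamycin; ALDOC under rapamycin stood at 7.46. The level of that control enters these falls too. Sterol and fatty acid genes fell in 13 of 23 cases with 0 higher (15 lower and 1 higher when adjusted over the list alone; camera, adjusted p = 9.19e-06). HMGCS1 fell by 0.91 ± 0.09. HSPA5 fell by 0.87 ± 0.09 and DNAJB9 rose by 0.84 ± 0.09. The reticulum list was not called, with 5 of 29 lower and 2 higher (6 and 2 when adjusted over the list alone; camera, adjusted p = 0.112). MKI67 rose by 0.52 ± 0.09, and replication genes were higher in 10 of 36 cases and lower in 1 (12 and 1 when adjusted over the list alone; camera, adjusted p = 0.000188, but adjusted p = 0.0985 with an estimated correlation). B-cell genes were higher in 13 of 26 cases and lower in 1 (15 and 1 when adjusted over the list alone; camera, adjusted p = 2.42e-05, but adjusted p = 0.0854 with an estimated correlation). The kinase gene PIM1 rose by 1.45 ± 0.10. Limma called 2336 of 9517 genes (1138 higher, 1198 lower), 230 of them at least 2-fold (43 higher, 187 lower). The count was 1339 without rapamycin replicate 1, and 1176 or 1477 without control replicate 1 or 2. Of the ONC201 signature, 58 of 98 rising genes were lower under rapamycin and 5 higher (camera, adjusted p = 1.09e-16, and 0.00321 with an estimated correlation). Of the 97 falling genes 25 were lower and 28 higher, with a median of -0.04 and a mean of 0.01 (camera, adjusted p = 0.741).

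Tunicamycin and rapamycin shared the untreated 24 h arrays, and their fold changes had an r of 0.268 across genes, against 0.501 in simulated unchanged groups. The covariance was 0.0550 against 0.00942, and 412 genes were higher in both and 487 lower in both where independent lists would share 196 and 184. Part of this excess may come from the shared controls.

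Finally the 24 h effect of ONC201 was set against those of the other compounds in JeKo-1 cells by testing the differences, each of which also holds the difference between a 0 h and a 24 h control and between 2 chips. Relative to tunicamycin, SDF2L1 differed by -3.20 ± 0.16, HSP90B1 by -2.30 ± 0.09, MANF, a secreted factor of the reticulum, by -2.30 ± 0.12 and HSPA5 by -2.07 ± 0.13 (n = 3 per group with ONC201 and 2 with tunicamycin). Lower and higher refer here, and for rapamycin below, to the difference of effects and not to levels. All 28 reticulum genes were lower, also when adjusted over the list alone (camera, adjusted p = 8.6e-27). The stress response list was not called, with 9 of 30 higher and 6 lower, also when adjusted over the list alone (camera, adjusted p = 0.83): DDIT4 differed by 1.32 ± 0.16, TRIB3 by 0.71 ± 0.11 and DDIT3 by -0.12 ± 0.15. The levels (log2) ran the other way, with DDIT4 at 10.55 with ONC201 and 11.12 with tunicamycin and TRIB3 at 12.33 and 12.64, as the controls at 0 h and 24 h stood at 8.22 and 10.10 for DDIT4 and at 8.67 and 9.69 for TRIB3. Genes induced by NF-kB and the B-cell receptor were higher in the difference in 14 of 21 cases and lower in 0 (18 and 1 when adjusted over the list alone; camera, adjusted p = 2.74e-11), for example CD83 by 1.87 ± 0.14. MYC targets were lower in 12 of 34 cases and higher in 0 (16 lower when adjusted over the list alone; camera, adjusted p = 1.46e-05). Limma called 2287 of 8600 genes (1145 higher, 1142 lower). Across genes the 2 effects had an r of 0.466, with 717 genes higher in both and 547 lower in both where independent lists would share 316 and 254.

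Relative to rapamycin, TRIB3 differed by 5.38 ± 0.11, STC2 by 5.24 ± 0.14, DDIT4 by 4.94 ± 0.16 and ATF5 by 4.37 ± 0.13 (n = 3 per group with ONC201 and 2 with rapamycin). The levels (log2) with ONC201 and with rapamycin were 12.33 and 7.97, 8.72 and 5.48, 10.55 and 7.50, and 12.77 and 9.21, in that order. The controls at 0 h and 24 h stood at 8.67 and 9.69, 6.05 and 8.05, 8.22 and 10.10, and 11.55 and 12.35. Part of each difference thus goes with the controls. Of the stress response genes 28 of 30 were higher in the difference and 0 lower (30 when adjusted over the list alone; camera, adjusted p = 6.88e-36). Replication genes were lower in 22 of 36 cases and higher in 2 (23 and 2 when adjusted over the list alone; camera, adjusted p = 2.95e-06). B-cell genes were lower in 17 of 25 cases and higher in 1 (18 and 3 when adjusted over the list alone; camera, adjusted p = 2.31e-06). MS4A1 differed by -2.03 ± 0.21. Limma called 2775 of 8600 genes (1426 higher, 1349 lower). Across genes the effects of ONC201 and rapamycin had an r of -0.0575.

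**Figure D4:**
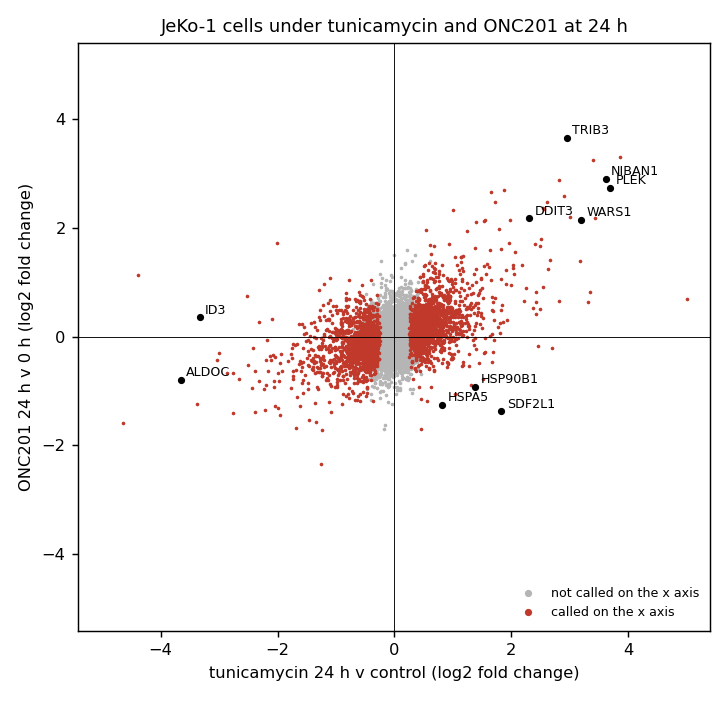
Log2 fold change at 24 h in JeKo-1 cells under ONC201 (vertical) against tunicamycin (horizontal); each point is a gene and red points are the genes called under tunicamycin. The points rise together (r of 0.466 across genes), while HSPA5 lies at 0.82 on the horizontal and -1.25 on the vertical axis.

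Further lists are given here at 24 h with ONC201 in JeKo-1 unless stated. The lists of amino acid synthesis, tRNA synthetases and mTORC1 regulators share genes with the stress response list, for example ASNS, WARS1 and DDIT4. They are thus not separate support. Genes of serine, one-carbon and amino acid synthesis rose in 9 of 12 cases and fell in 2 (10 and 2 when adjusted over the list alone; camera, adjusted p = 2.32e-05). Under rapamycin 9 of 13 fell with 0 higher (10 lower when adjusted over the list alone; camera, adjusted p = 1.71e-05, but adjusted p = 0.0711 with an estimated correlation). Cytosolic tRNA synthetase genes rose in 10 of 17 cases and fell in 4 (11 and 4 when adjusted over the list alone; camera, adjusted p = 0.00321, but adjusted p = 0.189 with an estimated correlation). Negative regulators of mTORC1 rose in 6 of 12 cases and fell in 1, also when adjusted over the list alone (camera, adjusted p = 0.00953, but adjusted p = 0.179 with an estimated correlation); without 0 h replicate 1 this adjusted p of camera was 0.0506. Lists that camera did not call were the p53 targets (5 of 16 higher, 4 lower; 6 and 4 when adjusted over the list alone; adjusted p = 0.215). The same holds for the interferon response, where IRF1 rose by 0.71 ± 0.10 and MX1 fell by 0.59 ± 0.08 (8 of 26 higher, 3 lower, also when adjusted over the list alone; camera, adjusted p = 0.461). It did not call the oxidative stress response (1 of 16 higher, 4 lower; 1 and 3 when adjusted over the list alone; camera, adjusted p = 0.534). Nor were the cytosolic ribosomal proteins (6 of 52 higher, 3 lower; 4 and 3 when adjusted over the list alone; camera, adjusted p = 0.462) and the mitochondrial chaperones and proteases (3 of 20 higher, 8 lower, also when adjusted over the list alone; camera, adjusted p = 0.225) called.

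Of 243 list tests over the 10 main comparisons, 121 passed with the preset correlation of camera and 36 also with an estimated correlation. As some lists share genes, these tests are not independent of each other. These 36 were the stress response list in all of these comparisons but resistant cells under ONC201 and tunicamycin at 24 h, and the reticulum list at 12 h in JeKo-1, in parental Z138, in the resistant minus parental difference and under tunicamycin at both times. The sterol and fatty acid list passed in JeKo-1 under every compound and time. The 36 also held the serine and amino acid list and the MYC targets at each time with ONC201 in JeKo-1, the replication list at 24 and 36 h in JeKo-1, in parental Z138 and in the resistant minus parental difference, and the mitosis list at 36 h. The rest were the heat shock list at 24 and 36 h in JeKo-1, the histone list in untreated resistant cells, and the NF-kB list there and under tunicamycin at both times. Of the signature tests and the differences between compounds, lines and times given above, those that camera called at the preset correlation also passed with an estimated correlation except where that p is printed.

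**Figure D5:**
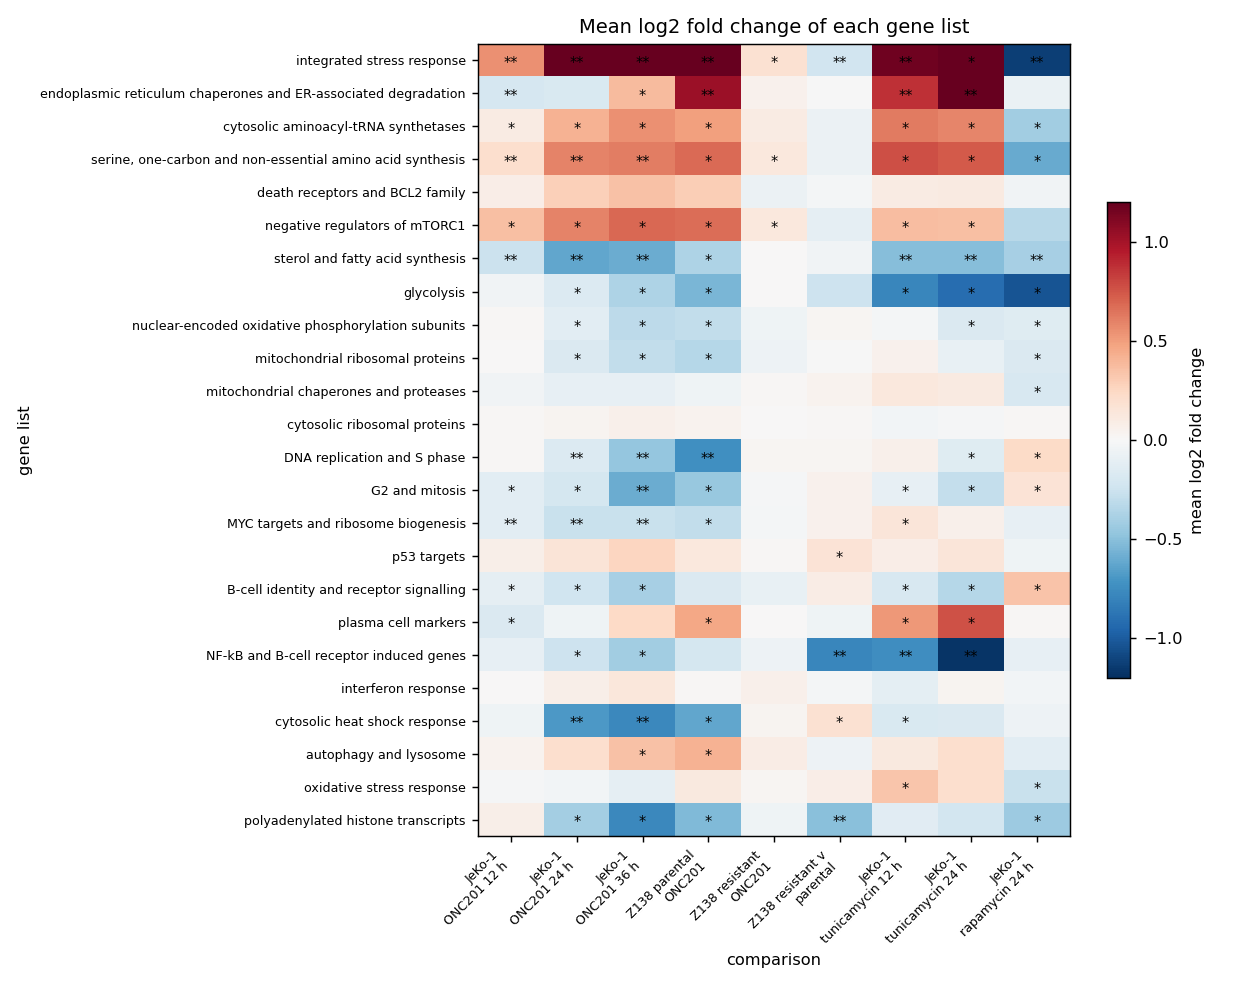
Mean log2 fold change of 24 gene lists (lines of the grid) in 9 comparisons (columns); colour runs from blue (lower) to red (higher), and the darkest colour covers all values beyond 1.2 in size. One asterisk marks an adjusted p of camera under 0.05 and a pair also with an estimated correlation; the stress response list has a mean of 1.34 under ONC201 at 24 h in JeKo-1 and -1.13 under rapamycin.

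Markers of other cell types were rarely measured: 2 of the T-cell and 3 of the myeloid genes passed the detection filter in the ONC201 course. There the myeloid gene TYROBP fell by 0.86 ± 0.20 at 24 h and the T-cell gene CD247 rose by 0.30 ± 0.07. Under rapamycin CD247 fell by 1.43 ± 0.09 and TYROBP rose by 0.90 ± 0.18. Each of these values is for a single gene and does not stand for its list, which held other measured genes. These lists had too few members to test in the ONC201 course, as did the stromal and epithelial markers in every experiment. HERPUD1 and TFAM were not analysed here, and CDKN1A and DRD2 did not pass the detection filter in any comparison.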

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

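Of the tests in this part, the comparison of 36 h with 24 h and the tests of the normalization and of the 0 h control were chosen after the result was seen, while the tests on resistant cells were written down first.

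The effect of ONC201 differed between resistant and parental Z138 cells in 2886 genes, and its effect at 24 h differed between JeKo-1 and parental Z138 cells in 2234, each by limma's test of the difference itself. Between 24 h and 36 h in JeKo-1, limma called 1275 genes. Among named genes, the tested difference of JeKo-1 minus Z138 was -2.86 for HSPA5, -2.26 for SDF2L1, -2.04 for HMGCS1, and -2.03 for HSP90B1. It was -1.66 for the secreted factor MANF, -1.56 for SYVN1, the ligase that marks misfolded proteins for degradation, -1.31 for the lectin chaperone CANX, -1.28 and -0.83 for the disulfide isomerases PDIA4 and PDIA6, and -0.76 for the translocon subunit SEC61B. These genes fell in JeKo-1 at 24 h and rose in parental Z138, where the call of HMGCS1 by limma was lost without treated replicate 1 (adjusted p = 0.0626) or control replicate 2 (adjusted p = 0.0584). Between 36 h and 24 h in JeKo-1, PDIA4 was higher by 0.68 and SEC61B by 0.46, after both had been lower than at 0 h at 24 h.

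For the reticulum genes that were lower under ONC201 in JeKo-1 than in Z138, the tables argue against the background correction and the offset as the cause. Under each of 4 other normalizations, 26 of 26 members were still called lower. The quantile step was not tested by itself, as all but the authors' normalized values, whose method is unknown, kept it. The 0 h control of JeKo-1 stays open: over these members the untreated cells at 24 h minus those at 0 h had a median of -0.14, within the range of random lists (-0.243 to 0.0895), but these 2 controls sit on different chips. The difference of the effects has a median of -1.19, and the shift differed between members. The mean levels (log2) in untreated cells at 0 h, with ONC201 at 24 h and in untreated cells at 24 h were 12.53, 11.61 and 11.65 for HSP90B1, 10.91, 9.54 and 10.02 for SDF2L1, and 9.5, 8.25 and 9.5 for HSPA5. Time and chip are not separable here, so how much of the difference goes with the control stays open. The unknown dose in JeKo-1, the timing of the response and the cell line itself are open and untested here.

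The 46 genes called under ONC201 in resistant Z138 cells were weighed against 3 explanations. A distortion that depends on signal stays open: the Spearman correlation across genes of fold change and mean signal was 0.0236, under the bound of 0.1 set for excluding it. That bound was wrong by design, since the quantile normalization gives all arrays one distribution and so removes most such trends itself. Spread between wells cannot be told apart from an effect: 1 of the 3 splits of the 4 arrays into 2 and 2, the real one, gave as many genes, with 0 in the highest other, and 3 splits are too few. A weaker form of the parental response also stays open, as 30 of the 46 genes went the parental way, which lies between the bounds set for it. Of the 46, 12 were called in parental cells in the same direction and 6 in the opposite direction. In both, 4 genes were higher and 8 lower, where independent lists would share 2.28 and 7.90. The 6 were higher in parental and lower in resistant cells, against 8.22 for independent lists, with 0 the other way against 2.19. These shared calls thus lie near the level of independent lists and add little to this explanation.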

How the results depend on the processing

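All alternatives were planned except the comparison of 36 h with 24 h, chosen after the data were seen. Main values are in parentheses.

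The count for ONC201 in resistant Z138 cells (46; 10 higher, 36 lower) moved most: 418 without background correction (176 higher, 242 lower), 454 with an offset of 50 (198 higher, 256 lower), 604 in one fit over all arrays (275 higher, 329 lower), 702 with trend and robust moderation (323 higher, 379 lower). It was 102 with the strict filter, 15 among all probes, and 0 with the authors' background-corrected values, with the authors' normalized values, with each experiment normalized alone, without a detection filter and with the replicate block. Leaving out an array gave 0 to 0. In one fit the other experiments lend degrees of freedom. For the rest the cause was not tested.

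For untreated resistant against parental cells (370), the authors' normalized values gave 222, no detection filter 205, one fit 623, trend and robust moderation 566, and leaving out an array 106 to 181. ONC201 at 12 h (337) had 519 genes in one fit, 218 with the replicate block and 159 to 296 with an array left out. The other arrays left out gave 1379 to 1515 for tunicamycin at 12 h (2429), 2016 to 2234 at 24 h (3101) and 1176 to 1560 for rapamycin (2336). With an array left out of a pair, the lone array is assumed to vary like the other groups. Fewer arrays give less precision, which tends to lower the counts. For the other settings the cause was not tested.

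Counting all probes instead of genes raised 4 counts by over 1.5 times by construction, as more probes than genes are tested: to 5112 at 24 h (3383), 7270 at 36 h (4502), 7156 at any time (4530) and 3454 for ONC201 minus tunicamycin (2287); the cause of the lower count in resistant Z138 cells, given above, was not tested. Asking for at least 1.5-fold lowered counts by construction: to 87 at 12 h, 811 at 24 h, 1595 at 36 h, 1685 at any time, 1920 in parental Z138 (4232), and 229 in untreated resistant cells. It left 1059 and 1495 for tunicamycin at 12 h and 24 h, 1005 for rapamycin, 1265 and 1570 for ONC201 minus tunicamycin and minus rapamycin (2775), 1141 for JeKo-1 minus Z138 (2234) and 245 between 36 h and 24 h (1275).

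Replicate numbers showed no clear pairing of the wells: over same-numbered arrays the correlations of deviations ran from -0.193 to 0.102 in the JeKo-1 course (18 pairs), -0.0651 to 0.0826 in Z138 (12 pairs) and -0.0429 to 0.0267 in the third experiment (12 pairs). With 2 wells per group the deviations mirror each other. Each correlation in Z138 and in the third experiment is thus the same for replicates 1 and 2. The block moved 2 of 14 counts by over 1.5 times, both given above.

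Of the shifts of gene lists, 121 in the main setting, 36 passed with an estimated correlation. Without background correction 239 of 243 list results kept their side and direction, and with the authors' normalized values 238, with 4 lost and 1 gained; with arrays left out 6751 of 6804 did, with 38 lost and 15 gained. Among the genes named, 1558 of 1673 results kept side and direction with the authors' normalized values, 1599 without background correction, 1580 without a detection filter, and 1596 with an offset of 50. The number was 1543 with trend and robust moderation, 1615 with the block, and 9449 of 10234 with an array left out. With an offset of 50, the difference of JeKo-1 minus Z138 for SESN2 reversed to -0.037 (0.65 ± 0.17); its probe was not detected at 0 h in JeKo-1, and a larger offset shrinks dim signals more.

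Signal over background limits the dim genes: 29.7% to 35.2% of probes were detected on an array, folds of genes absent in a group are bounds, and the simulations recovered few changes of 0.5 in differences of 2 effects.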

Other observations

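The test of all 3 times together and the splits at single times were planned; the comparison of 36 h with 24 h and the tests on glycolysis genes, mitochondrial genes and untreated resistant cells were chosen after the result was seen.

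The 2 sets of untreated JeKo-1 cells, at 0 h in the ONC201 course and at 24 h beside tunicamycin and rapamycin, sit on different chips, so time and chip are not separable. Their mean levels (log2) were 5.07 and 9.06 for PFKFB4, 9.14 and 10.80 for ALDOC, and 6.95 and 8.74 for the mitochondrial adenylate kinase AK4. They were 6.05 and 8.05 for STC2, 8.22 and 10.10 for DDIT4, and 8.67 and 9.69 for TRIB3. Of the chaperone genes, HSP90B1 stood at 12.53 and 11.65, SDF2L1 at 10.91 and 10.02, and HSPA5 at 9.5 in both. With ONC201 at 24 h the levels were 6.20 for PFKFB4, 8.35 for ALDOC, 6.89 for AK4, 8.72 for STC2, 10.55 for DDIT4 and 12.33 for TRIB3. With tunicamycin at 24 h they were 4.67 for PFKFB4, 7.14 for ALDOC, 6.57 for AK4, 9.70 for STC2, 11.12 for DDIT4 and 12.64 for TRIB3. Under rapamycin they were 5.21 for PFKFB4, 7.46 for ALDOC, 5.91 for AK4, 5.48 for STC2, 7.50 for DDIT4 and 7.97 for TRIB3.

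Glycolysis genes were lower under both tunicamycin and rapamycin, which share their control. Over the 14 members lower under both, a raised level in the shared control was tested as the untreated cells at 24 h minus those at 0 h: the median was 0.25, above the range of random lists (-0.286 to 0.125), with 85.7% of the members higher. These members were chosen as lower against that same control, which favours genes that read high in it. The random lists were matched on mean signal only, so a shift above their range may be built in by the choice. Whether a raised control accounts for part of the fall, whose median was -0.78, stays open. It cannot be told apart from an effect of the compounds, because the chips differ as well as the times. The shift is also smaller than the bound set for it. The background correction and the offset are argued against, as 13 of the 14 were still lower under both with the normalization that kept fewest. All but the authors' normalized values kept the quantile step, which was not tested by itself. In the ONC201 course, on another chip, 5 of 20 glycolysis genes were lower at 36 h than at 24 h and 0 higher. Camera called this list at an adjusted p of 0.00501, but not with an estimated correlation (adjusted p = 0.173). Against 0 h, ALDOC stood at -0.79 at 24 h and -1.36 at 36 h, and PGAM1 at -0.80 and -1.14. At 24 h PFKFB4 and ENO2 were at least 1.62-fold and 1.03-fold higher than at 0 h.

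Since ONC201 activates a mitochondrial protease, a fall of mitochondrial genes found with ONC201 and not with tunicamycin was tested as a hypothesis, with the bound tightened after the values were seen. For mitochondrial ribosomal proteins the mean difference, ONC201 minus tunicamycin at 24 h in JeKo-1, was -0.080 (camera, adjusted p = 0.437), and for subunits of oxidative phosphorylation it was 0.046 (camera, adjusted p = 0.474). Neither list was called in the difference, so whether such a fall goes with ONC201 alone stays open.

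A standing response like that to ONC201 was looked for in untreated resistant Z138 cells with the genes of the signature that rise in JeKo-1. Their median, resistant minus parental, was -0.15, with 14 of 84 lower and 0 higher. These values argue against a standing rise of this set of genes, in a test chosen after they were seen. The set was taken against 0 h and so also holds time in culture. Whether a standing response to ONC201 itself is present stays open. Whether resistance goes with the lower level of these genes was not tested, and the labels do not say whether the line had been kept with the compound.

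For the counts of genes in the JeKo-1 course, the same arrays were split in other ways. The real split of 3 and 3 was the 1 of 10 with as many genes at 12 h (337, highest other 0), at 24 h (3383, highest other 1), at 36 h (4502, highest other 0) and between 36 h and 24 h (1275, highest other 0). These 10 splits are too few for a share under 0.05. For the F test over all times, 1 of 100 splits, the real one, gave as many genes (4530, highest other 3291). That share is the smallest that 100 splits can give. It argues against an arbitrary grouping of the arrays as the source of the count. It cannot tell an effect of ONC201 from time in culture or place on the chip.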
